A study of Homo sapiens with 14 samples.

How the data were processed

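Gene expression was measured in 14 established human cell lines of diffuse large B-cell lymphoma, an aggressive cancer of B lymphocytes. The labels class 8 lines as sensitive to rapamycin, an inhibitor of the MTOR kinase, and 6 lines as resistant. Per the labels, cells were harvested in log phase, total RNA was extracted and biotin-labelled, and each line was read on 1 Affymetrix HuGene ST 1.0 array. The replicates of a group are therefore samples labelled as different cell lines, with 1 array each, and the number of arrays limits the precision of every value. No label says how sensitivity was measured, and the labels name no drug treatment of the arrayed cells.

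The deposited values are log2 expression levels, 1 per feature and array. Per the submitters' processing notes they were made with RMA in Affymetrix Expression Console; the software version and the genome build are not given in the sources used here. RMA subtracts background, forces the arrays onto 1 distribution and summarises the probes of a feature, so a change shared by most genes of a line is removed, and levels near the lower end of the scale differ by less than the RNA does. The deposited log2 table held 33297 features with values from 1.69 to 14.0, and the scale was read from these values. Array medians lay between 5.56 and 5.69, and genes were not centred.

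Features were named through the platform annotation. Of the features, 19460 carried 1 gene symbol, 1754 carried several and 12083 had none listed. Current symbols were found by Entrez identifier for 19429 features, and 0 symbols needed updating. Features with 1 symbol were used, and for the 769 genes with several such features the brightest stood for the gene, which left 18417 genes. No filter on level was applied.

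Sensitive and resistant lines were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided, no covariates) and Benjamini-Hochberg adjustment over all genes at 0.05. Differences are sensitive minus resistant on the log2 scale, with the standard error (SE) from limma. Gene lists fixed before the data were examined were tested with camera at its preset inter-gene correlation of 0.01, two-sided and adjusted over the 30 lists of 31 that had at least 5 measured members. The remaining list had no measured member and was not analysed here. Camera was repeated with the correlation estimated from the data, and the lists were also tested with fry and with an exact permutation of each list's mean standardised level over all 3003 splits of the 14 lines into 8 and 6. A panel of 18 genes around MTOR, AKT and lymphoma biology, 16 of them measured, was tested gene by gene with exact two-sided permutation tests. For classification, each line was left out in turn, the 50 genes with the smallest limma p among the other lines were taken, and the line was given to the class whose centroid it correlated with best.

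Genes were named by a rule fixed before the data were examined. It took the 12 genes with the smallest p in each direction among those differing by at least 1 log2 unit, the panel, and up to 4 members with the smallest p of each list described. Sex-linked marker genes, immunoglobulin and T-cell receptor segments, uncharacterised loci and features with several symbols were left out of the naming. Panel members without a feature of their own are not analysed here.

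Alternatives fixed beforehand were SAM (a permutation-based statistic that the series names, written anew here with 100 permutations), an intensity trend with robust moderation, unmoderated statistics, array quality weights, repeated quantile normalization, median centring, the brighter genes alone, every feature of the table, the mean of a gene's features, the run of sample identifier numbers in the labels as a block, the 9 lines of the largest run alone, omission of the 3 lines grown in Iscove's medium, omission of OCI-Ly3 and OCI-Ly10, a threshold of 0.1, omission of each line in turn, and signatures of 20, 100 or 200 genes. Averaging, omitting, blocking or jointly holding out OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18 was chosen after seeing the data, as was the repetition of SAM, array quality weights and every feature on the averaged lines.

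The scripts were tested on simulated data for the comparison of sensitive with resistant lines over 18417 genes. Limma recovered 69% of 100 genes changed by 1 log2 unit and 91% of 100 genes changed by 2, with 7 unchanged genes called. With no gene changed it called 0, and with 200 changed genes 14 of 14 lines were classified correctly. The simulated values were drawn independently for each gene and line. They hold no lines that resemble each other and no genes that move together. The test therefore checks the scripts, and its shares do not give the power reached with the 14 measured lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.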

Results

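Expression levels were measured on 1 array for each of 14 lines of diffuse large B-cell lymphoma. The sensitive group held OCI-Ly1, OCI-Ly3, OCI-Ly4, OCI-Ly10, OCI-Ly18, Farage, WSU-NIH and SUDHL6, and the resistant group held OCI-Ly19, SUDHL8, Karpas 422, Pfeiffer, Toledo and SUDHL4. The series asked which genes separate lines that respond to rapamycin from lines that do not, with the MTOR and AKT pathway as its subject. Levels are log2 RMA values, given as mean ± SD over 8 sensitive and 6 resistant lines.

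The profiles of 4 sensitive lines were nearly the same. Among OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18 the 6 pairwise Pearson correlations across genes lay between 0.987 and 0.995, and 2 to 28 genes differed by over 4-fold within a pair. The other 85 pairs of lines had correlations of 0.899 to 0.958 and 242 to 842 such genes. OCI-Ly3 and OCI-Ly18 differed by over 4-fold at 3 genes, CD44, CCND2 and CYB5A, and OCI-Ly4 and OCI-Ly10 at 2 genes, ZNF737 and DDX60. These 4 lines make up 4 of the 8 sensitive samples, so the counts of called genes, called lists and classified lines are also given with them averaged to 1 line, which leaves 5 sensitive against 6 resistant lines.

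**Figure D1:**
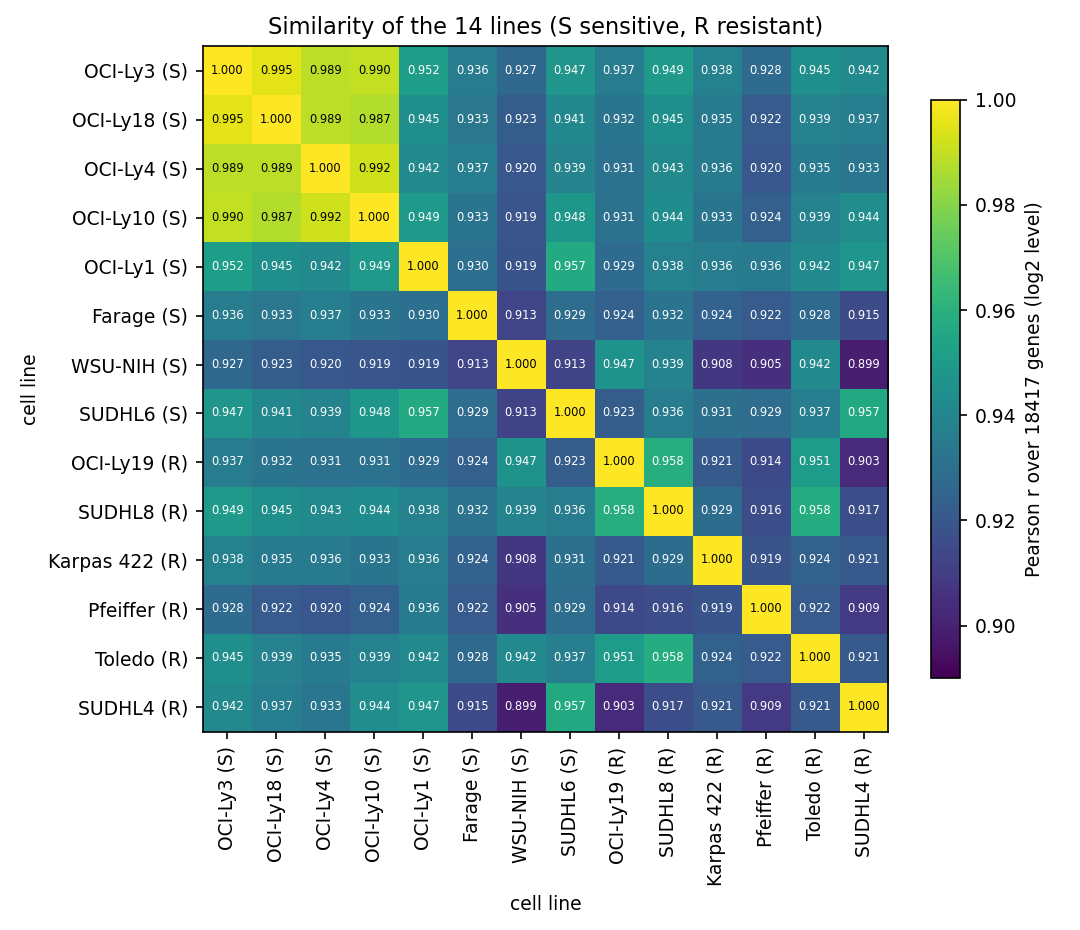
Pearson correlation of log2 levels over 18417 genes for each pair of the 14 lines (color, with the value in each cell; S sensitive, R resistant). OCI-Ly3, OCI-Ly18, OCI-Ly4 and OCI-Ly10 form a block at 0.987 to 0.995, while the other pairs lie between 0.899 and 0.958.

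None of the 12 genes with the smallest p and a higher level in sensitive lines passed adjustment. HVCN1, a voltage-gated proton channel, had a level of 8.81 ± 0.93 in sensitive and 6.16 ± 1.01 in resistant lines, a difference of 2.64 (SE 0.49, adjusted p = 0.636 in limma). ATP2B1, a calcium pump of the plasma membrane, differed by 1.39 (SE 0.26). The tetraspanin CD53 differed by 1.72 (SE 0.36), and its groups did not overlap: sensitive lines lay between 11.32 and 12.43 and resistant lines between 8.15 and 10.80. EVI2B differed by 2.56, the lymphoid phosphatase PTPN22 by 2.63, the lymphocyte receptor SLAMF1 by 2.27, TLR4, the receptor for lipopolysaccharide, by 2.02 and the Fc receptor-like protein FCRL5 by 1.74. SYNE2, BPHL, TCTN1 and RAB8B completed the set, with differences of 1.53, 1.07, 1.05 and 1.24. Averaging the 4 near-identical lines made each difference of this set smaller except that of SLAMF1 (2.28). TLR4, FCRL5, BPHL and TCTN1 then came to 1.56, 1.45, 0.82 and 0.82, and HVCN1 to 2.41.

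None of the 12 genes with the smallest p and a lower level in sensitive lines passed adjustment either. MYBPC2, a myosin-binding protein, had a level of 5.13 ± 0.43 in sensitive and 6.54 ± 0.76 in resistant lines, a difference of -1.41 (SE 0.30, adjusted p = 0.636 in limma). DCP1B, a cofactor of mRNA decapping, differed by -1.48, the phosphatidylcholine transfer protein PCTP by -1.57 and the glutathione transferase GSTO1 by -1.97. Of the remaining genes DMXL2, MKS1 and LPGAT1 differed by -1.61, -1.49 and -1.30, and IQSEC1, REPIN1, TSPYL4, RGMB and HEBP2 by -1.13 to -1.01. With the 4 near-identical lines averaged, each difference of this set was smaller in size. REPIN1, TSPYL4, RGMB and HEBP2 then came to -0.96, -0.91, -0.94 and -0.62, and DCP1B and GSTO1 to -1.10 and -1.42.

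**Figure D2:**
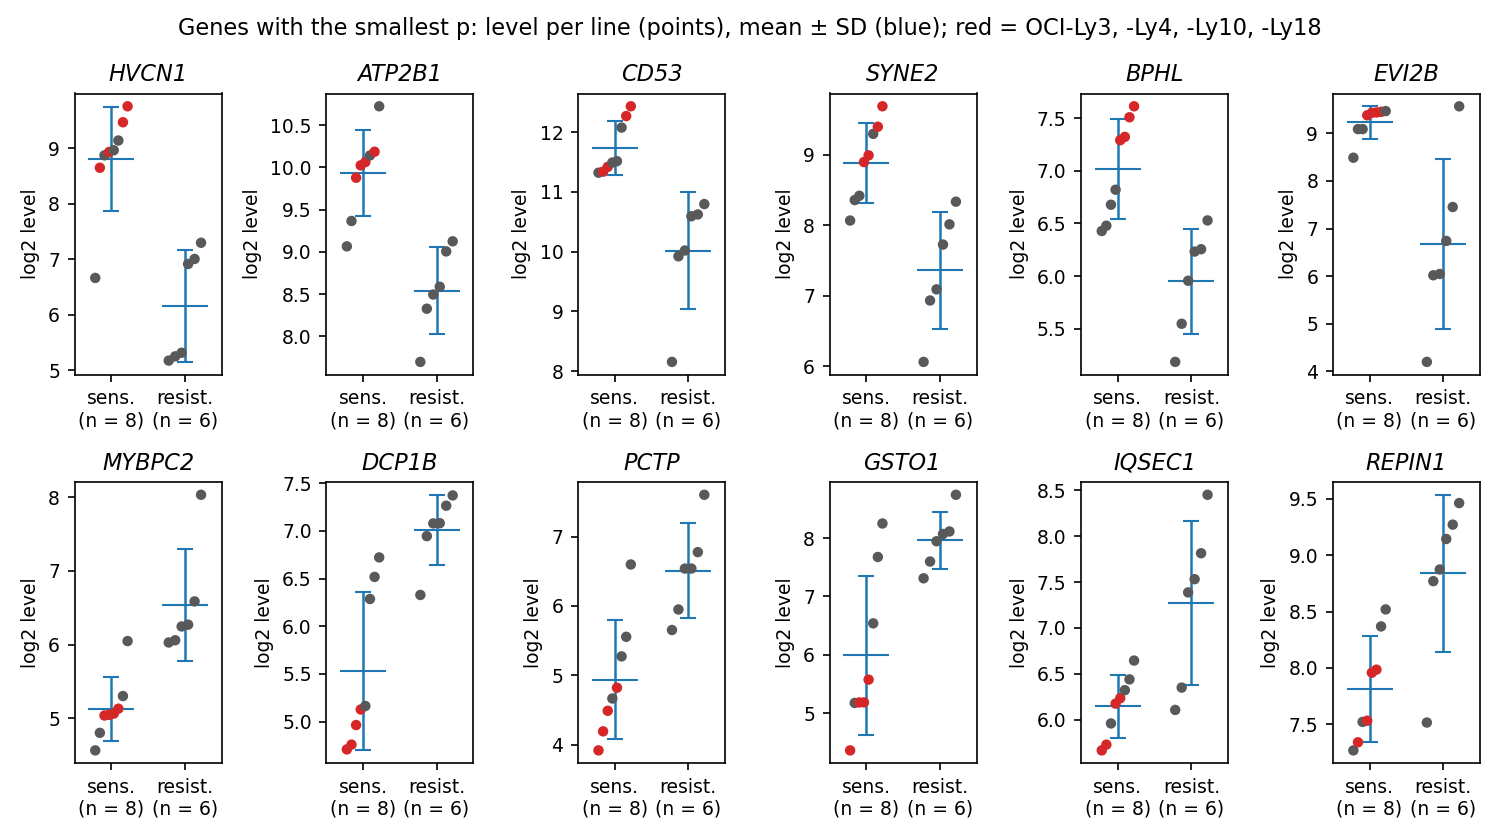
Log2 level of the 6 genes per direction with the smallest p, in 8 sensitive and 6 resistant lines (points; OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18 in red), with the mean ± SD of each group in blue. HVCN1 has means of 8.81 and 6.16, and of the genes drawn CD53 alone shows no overlap between the groups.

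Over all 18417 genes, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.636. At an unadjusted p under 0.05 it found 943 genes, 455 higher and 488 lower in sensitive lines, where 921 would pass by chance. With the 4 lines averaged it called 0 again, with 339 genes at an unadjusted p under 0.05. The groups did not overlap for 15 genes, against 12.3 expected from random splits. SAM called 7 genes higher and 0 lower: HVCN1, ATP2B1, CD53, WAPL, INPP5B, ZBTB4 and ATXN10. Array quality weights gave 24 calls, 15 of them higher, among which were HVCN1, EVI2B, PTPN22, MYBPC2 and DCP1B. With the 4 lines averaged, SAM called 0 genes and array quality weights 0, with 848 at an unadjusted p under 0.05 in the weighted fit, and the groups did not overlap for 28 genes against 79.7 expected. WAPL, INPP5B, ZBTB4 and ATXN10 were named after their values were seen.

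When every feature of the array was tested, limma called 2 of 33297, and both had no gene listed in the annotation used, so whether they measure a transcript or are control features of the array is not known. Feature 7896697 had a level of 11.59 ± 0.48 in sensitive and 5.15 ± 0.57 in resistant lines (adjusted p = 1.76e-08 in limma). Sensitive lines lay between 10.49 and 11.96 and resistant lines between 4.22 and 5.75. Feature 7896715 gave 11.57 ± 0.48 and 4.86 ± 0.64 (adjusted p = 1.76e-08 in limma). With the 4 lines averaged limma again called 2 features, and the differences were 6.27 and 6.52 (adjusted p = 1.50e-05 in limma for both). These features were singled out after their values were seen.

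Components of the PI3K, AKT and MTOR pathway did not separate the groups. Of 32 measured members, 19 had a higher and 13 a lower mean level in sensitive lines (15 higher with the 4 averaged), and limma called 0 both over all genes and adjusted over the list alone, with 0 members at an unadjusted p under 0.05. AKT1 had a level of 8.85 ± 0.37 in sensitive and 9.06 ± 0.47 in resistant lines, a difference of -0.21 with a 95% interval of -0.68 to 0.25 (exact permutation p = 0.373), and of -0.09 with the 4 lines averaged. AKT2 differed by 0.12 (exact permutation p = 0.434) and MTOR by 0.29 (exact permutation p = 0.182). EIF4EBP1, which encodes the translation repressor 4E-BP1, had a level of 7.03 ± 1.34 in sensitive and 8.17 ± 0.95 in resistant lines (exact permutation p = 0.10), and its difference of -1.14 became -0.45 with the 4 lines averaged. SGK1, a kinase related to AKT, differed by 1.45 (SE 0.73), PIK3R5 by 0.26 and the MTOR activator RHEB by -0.35, and with the 4 lines averaged by 1.34, 0.14 and -0.10. Over the 16 panel genes the smallest adjusted permutation p was 0.730. RPTOR, RICTOR, DEPTOR, TSC1, TSC2, RPS6KB1, EIF4E and FKBP1A, the binding protein of rapamycin, had differences between -0.07 and 0.33, and the lymphoma genes BCL2, BCL6, IRF4 and MYC had differences of -0.44, 1.45, -0.58 and 0.20. With the 4 lines averaged, 5 of these differences had the other sign: BCL2 to 0.09, IRF4 to 0.01, DEPTOR from 0.33 to -0.60, TSC1 from 0.24 to -0.03 and FKBP1A from 0.06 to -0.02. The list as a whole had a camera adjusted p of 0.308.

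Camera called 5 of 30 gene lists, all higher in sensitive lines. Germinal centre markers, genes of the B-cell stage from which many of these lymphomas arise, had 17 of 19 members higher and a mean difference of 0.64 (adjusted p = 0.000395, and adjusted p = 0.819 with an estimated correlation). IRAG2 had a level of 11.79 ± 0.30 in sensitive and 10.66 ± 0.97 in resistant lines, BCL6, a repressor that maintains the germinal centre state, differed by 1.45, STAP1 by 1.84 (1.15 with the 4 averaged) and LMO2 by 0.45. Single lines went the other way: in mean standardised level the resistant line SUDHL4 (0.71) lay above the highest sensitive line (0.45) and resistant Karpas 422 was at 0.43, while sensitive WSU-NIH was at -0.56. B-cell receptor signalling genes had 19 of 29 members higher and a mean difference of 0.49 (adjusted p = 0.00328, and adjusted p = 0.819 with an estimated correlation). The B-cell receptor inhibitor CD22 had a level of 10.27 ± 0.60 in sensitive and 8.23 ± 1.76 in resistant lines, the complement receptor CR2 differed by 3.21 (2.05 with the 4 averaged) and CD72 by 1.42, while SOS1 differed by -0.57. SUDHL4 had the highest list score here too (0.64). Camera did not call activated B-cell-like markers (adjusted p = 0.742) or B-cell identity genes (0.393). Targets of the tumour suppressor p53 had 19 of 28 members higher and a mean difference of 0.26 (adjusted p = 0.00664, and adjusted p = 0.819 with an estimated correlation). Among them MDM2 differed by 1.09 (SE 0.35), TP53INP1 by 1.34, ZMAT3 by 0.74 and PLK3 by 0.29.

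Interferon-stimulated genes had 24 of 32 members higher and a mean difference of 0.50 (adjusted p = 0.000395, and adjusted p = 0.975 with an estimated correlation). IFI44L had a level of 7.27 ± 3.32 in sensitive and 4.50 ± 0.77 in resistant lines, IFI27 of 7.70 ± 2.26 and 5.69 ± 0.13, IRF9 differed by 0.76, and SAMD9 differed by -1.16. With the 4 lines averaged, IFI44L, IFI27, IRF9 and SAMD9 differed by 0.96, 0.84, 0.51 and -0.64. Cytosolic ribosomal protein genes had 29 of 34 members higher and a mean difference of 0.10 (adjusted p = 0.000645, and adjusted p = 0.975 with an estimated correlation), with RPS19, RPLP1, RPL35 and RPS24 at 0.33, 0.24, 0.20 and 0.47, and at 0.28, 0.24, 0.06 and 0.05 with the 4 averaged. With the 4 lines averaged the interferon and ribosomal lists were no longer called (adjusted p = 0.249 and 0.597, with 21 of 32 and 22 of 34 members higher), and without the 4 lines their direction turned (adjusted p = 0.534 and 0.357). The germinal centre, B-cell receptor and p53 lists kept the call with the 4 averaged (adjusted p = 0.00598, 0.00598 and 0.00368, with 16 of 19, 18 of 29 and 21 of 28 members higher). Cholesterol biosynthesis and replication-dependent histones were called there too (adjusted p = 0.000467 and 0.00598), again 5 of 30. With an estimated correlation none of these 5 was called, at adjusted p = 0.804 for the p53 list and 0.959 for the other 4. Omission of 1 line from the 14 also ended calls, that of the B-cell receptor list at adjusted p = 0.106 and that of the p53 list at 0.0630. Fry called 0 lists over the 14 lines. The exact permutation of list scores and the estimated correlation called 0 both over the 14 lines and with the 4 averaged. In the unweighted fit no list had a member past adjustment over all genes.

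**Figure D3:**
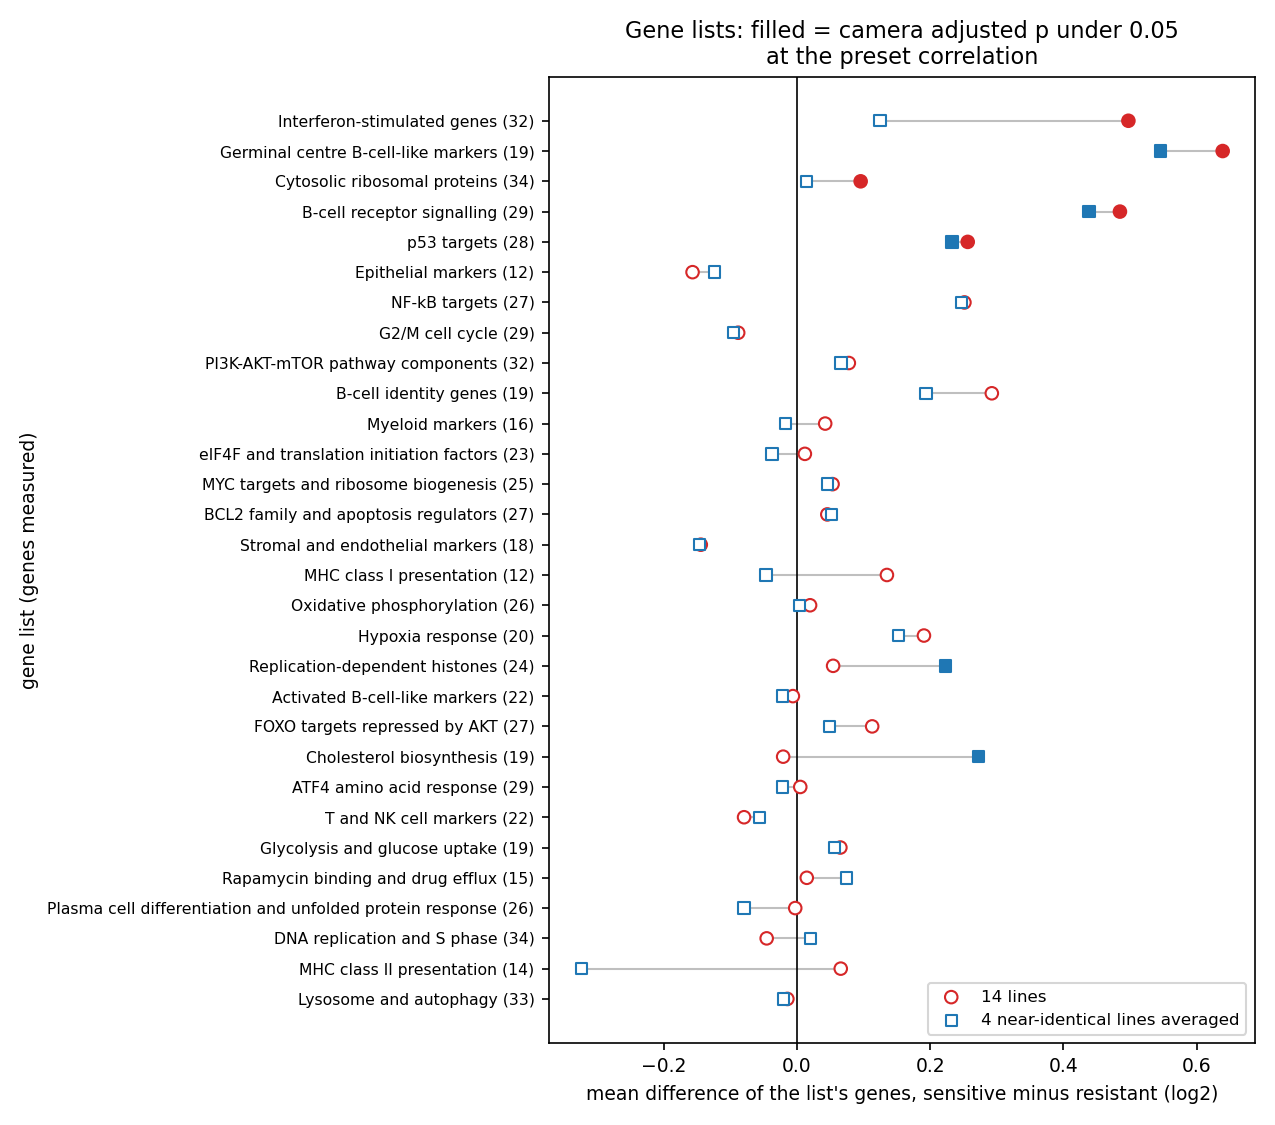
Mean log2 difference, sensitive minus resistant, of the genes of each of 30 lists (genes measured in brackets), with 14 lines (red circles) and with OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18 averaged (blue squares); filled symbols have a camera adjusted p under 0.05 at the preset correlation. The interferon list moves from 0.50 to 0.12, and the germinal centre list from 0.64 to 0.55.

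Outside the called lists, some members passed adjustment over their list alone while the list was not called. Each of the 30 lists was adjusted on its own, with no correction for the number of lists, so such calls can arise by chance. EIF3I, a subunit of an initiation factor, differed by 0.31 (SE 0.07) and was the 1 of 23 translation initiation factors under 0.05 when adjusted over the list alone. Among 27 apoptosis regulators BIK, a pro-apoptotic member of the BCL2 family, differed by 0.96 (SE 0.25) and was the 1 under 0.05 when adjusted over the list alone. BCL2L11, which encodes BIM, differed by -0.94 and BCL2L1 by -1.04. The amino acid transporter SLC7A5 differed by -0.68 and was the 1 of 29 amino acid response genes under that threshold, and the oxygen sensor EGLN1 differed by -0.88 and was the 1 of 20 hypoxia genes. In the unweighted fit limma called none of these over all genes, while with array quality weights EIF3I and EGLN1 passed (adjusted p = 0.0463 for each). With the 4 near-identical lines averaged, 0 of the 4 calls over the list alone were left: the differences of EIF3I, BIK, SLC7A5 and EGLN1 were then 0.25, 0.94, -0.70 and -0.67 (list-adjusted p = 0.242, 0.323, 0.118 and 0.176). Over the 14 omissions of 1 line the calls were met in 12, 4, 6 and 14, and the highest list-adjusted p was 0.0600 without Karpas 422 for EIF3I, 0.136 without SUDHL8 for BIK, 0.0996 without Karpas 422 for SLC7A5 and 0.0497 without Toledo for EGLN1. Camera gave NF-kB targets an adjusted p of 0.0872, MYC targets and ribosome biogenesis 0.504, glycolysis 0.806, oxidative phosphorylation 0.684, FOXO targets 0.775, G2/M genes 0.293 and genes of rapamycin binding and drug efflux 0.865. Marker lists of T and NK cells, myeloid, stromal and epithelial cells had adjusted p of 0.797, 0.490, 0.582 and 0.0684. Of the 12 epithelial markers 11 had a lower mean level in sensitive lines, and camera called the list in 5 of the omissions of 1 line (lowest adjusted p = 0.0122). NF-kB targets were called in 3 (lowest 0.000706). The epithelial markers had a mean level of 5.43, under the lowest array median of 5.56, and a mean difference of -0.16. Their list scores in resistant lines ran from -0.47 in OCI-Ly19 to 1.85 in Pfeiffer.

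A signature learned from the other lines placed 7 of 14 left-out lines in their own class. These were 4 of 8 sensitive lines, exactly OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18, and 3 of 6 resistant lines, OCI-Ly19, Pfeiffer and Toledo. When the 4 near-identical lines were held out together, 3 of 14 lines were placed correctly, among them 0 of the 4. With the 4 averaged 1 of 11 lines was placed correctly, and without them 3 of 10.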

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

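In this part the tests of the 4 near-identical lines, of the 5 called lists and of the joint hold-out were chosen only after the results were seen, and the counts of other splits were fixed before them.

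Within their groups, 14 values stood far from the rest among 140 groups of values checked, and chance marks about 1 in 20. Among sensitive lines, OCI-Ly1 had a low HVCN1 (6.66) and a high RPTOR (9.22), Farage a low EVI2B (8.49), SUDHL6 a low RPS6KB1 (8.46). Among resistant lines, Pfeiffer had a low CD53 (8.15) and a high RPTOR (7.40), Toledo a high FCRL5 (5.59), Karpas 422 a high MYBPC2 (8.03) and a low REPIN1 (7.52), and SUDHL4 a low MTOR (7.57). Of the list scores, given as mean standardised levels, WSU-NIH stood apart in germinal centre markers (-0.56) and DNA replication (0.80), Farage in NF-kB targets (1.55), and Pfeiffer in plasma cell and unfolded protein response genes (1.07).

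The pattern most in need of follow-up is the near-identity of OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18. Of 672 genes that range over 4 log2 units or more among the other 10 lines, 2.23% differed by over 2 log2 units among these 4, against 54.0% to 90.6% in the 210 sets of 4 of the other lines, which restates the near-identity and decides nothing about its origin. A shared medium is argued against as the whole cause, since the 4 pairs of these lines grown in different media lay within a root mean square log2 difference of 0.332, while the 56 other pairs grown in 1 medium lay at 0.589 or more. Handling together, as far as neighbouring identifier numbers show it, is argued against by the 9 other pairs of neighbouring numbers, of which the closest lay at 0.589, and shared sensitivity by the other sensitive lines, of which the nearest lay at 0.627. It stays open whether these are 1 line, or a cross-contaminated stock, under 4 names, or whether cultures, RNA or arrays were shared, and line identity needs genotyping.

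The interferon and ribosomal protein lists may owe their calls to these 4 lines being counted as 4, since with the 4 averaged the smaller adjusted p was 0.249. The 4 were not all high in both lists. In mean standardised level of the interferon list, OCI-Ly4 was at 1.44 and OCI-Ly10 at 0.80. OCI-Ly3 (0.25) and OCI-Ly18 (0.14) lay below resistant Karpas 422 (0.49) and OCI-Ly19 (0.29). In the ribosomal list OCI-Ly3 was at 1.28 and OCI-Ly18 at 1.25. OCI-Ly10 was at 0.32 and OCI-Ly4 at 0.02 there, with resistant SUDHL4 at 0.28. For the germinal centre, B-cell receptor and p53 lists the camera calls at the preset correlation did not need the 4 counted as 4. The largest adjusted p with the 4 averaged was 0.00598 there. At that setting each of the 99 other splits of the 14 lines also called at least 2 lists. The kept calls therefore say little about a difference between the groups. Genes of a list moving together between lines could account for both sets of calls. With the correlation estimated, the smallest adjusted p in camera was 0.975 for the first set and 0.819 for the second. The case is weakest for the p53 list, with an estimated correlation of 0.05, against 0.38 for the interferon and 0.42 for the ribosomal list. Its camera p at that correlation was 0.031 before adjustment over the lists and 0.819 after it. Chance could not be excluded: 80 of 100 splits of the 14 lines called as many lists as the real 5, and the highest other split called 14. A difference tied to rapamycin response stays open and untested.

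The 7 of 14 lines classified correctly may rest on near-identical lines standing in for each other, since 0 of the 4 were placed with the sensitive class once all 4 were held out. Chance could not be excluded, as 59 of 100 splits classified as many lines and the highest other split 12. Any split reaches a count of 0, so the 100 of 100 splits for the genes, and the 100 of 100 for the PI3K, AKT and MTOR genes, say nothing about chance. The highest other counts were 58 and 5. Of 99 other splits, 7 called any gene, 6 of them among the 12 that kept the 4 near-identical lines in 1 group, a comparison made after the results were seen.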

How the results depend on the processing

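Settings that treat OCI-Ly3, OCI-Ly4, OCI-Ly10 and OCI-Ly18 in a special way were chosen only after the data were seen, and the other settings were fixed before. The number of genes called was 0 in limma, but 7 with SAM, 24 with array quality weights and 2 over every feature; it was 0 under the remaining settings, each line left out included. With the 4 averaged it was 0 with SAM, 0 with array quality weights and 2 over every feature. The weights were 1.71 to 3.91 for the 4 near-identical lines and 0.388 to 1.51 for the others, so that fit leaned on lines that resemble each other. The number of lists called was 5, and 8 in the 9 lines of the largest identifier run, 8 without the Iscove lines, 0 with camera's estimated correlation, 0 with fry, 0 with the exact permutation, 0 with the 4 averaged and the correlation estimated, and 4 to 7 with a line left out. The cause was not tested. Leaving out 1 line ended the call of 4 lists: ribosomal proteins without OCI-Ly18 (adjusted p = 0.0508), interferon genes without SUDHL4 (0.0517), B-cell receptor genes without OCI-Ly19 (0.106) and p53 targets without Farage (0.0630). It also brought calls of other lists: epithelial markers without OCI-Ly1, OCI-Ly10, OCI-Ly19, SUDHL8 or Karpas 422 (lowest adjusted p = 0.0122), NF-kB targets without OCI-Ly1, Pfeiffer or WSU-NIH (lowest 0.000706), G2/M genes without Farage, Pfeiffer or Toledo (lowest 0.0296), MYC targets without OCI-Ly19 (0.0168) and histones without OCI-Ly4 (0.0481). Over all settings the epithelial list was called in 9 of 29, NF-kB targets in 7, histones in 6 and cholesterol genes in 4 of 30, and DNA replication, MHC class II, hypoxia and B-cell identity genes in 1 each. With the identifier run as a block the interferon list had an adjusted p of 0.0654, and without the Iscove lines 0.155. The p53 list had 0.0565 with array quality weights, and the adjusted p of Cytosolic ribosomal proteins was 0.0767 without OCI-Ly3 and OCI-Ly10. Without the 4 lines the interferon and ribosomal lists were reversed, at adjusted p = 0.534 and 0.357. The count of PI3K, AKT and MTOR genes stayed at 0 under every setting run. Lines classified correctly were 7 of 14, and 3 of 12 without OCI-Ly3 and OCI-Ly10, 3 of 14 with the 4 held out together, 1 of 11 with them averaged and 3 of 10 without them; other settings gave 5 to 8 of 14, or 5 of 11 without the Iscove lines. The 24 genes with the smallest p kept their direction in 615 of 615 recalculations, 10 of which passed adjustment, all with array quality weights. These genes were chosen for their differences in the same arrays, so a change of sign was unlikely from the start. Panel genes had the other sign in 35 of 415 recalculations, and none passed adjustment: DEPTOR in 7, RPTOR, EIF4E and FKBP1A in 5 each, IRF4 and RPS6KB1 in 3, BCL2, TSC1 and RICTOR in 2 and EIF4EBP1 in 1. No paired analysis was possible because the labels pair no sensitive with a resistant sample. Levels near the lower end of the scale cannot be told from background here, since no detection values were used.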

Other observations

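The markers of individual lines described here were chosen after their values were seen. MTAP, a methionine salvage enzyme, had levels of 4.50 and 4.49 in the resistant lines OCI-Ly19 and SUDHL8, and 6.73 to 8.03 in the other 12 lines. MS4A1, which encodes CD20, had a level of 4.20 in OCI-Ly19 and 5.12 in WSU-NIH, against 7.43 in SUDHL8 and 9.40 or more elsewhere, whereas the B-cell factor PAX5 lay between 9.63 and 10.50 in all 14 lines. Farage had the highest IL10 (7.44, with 4.90 or less elsewhere), ENTPD1 (10.71) and EBI3 (9.26). SERPINA9, a germinal centre marker, reached 10.97 in Karpas 422 and 9.65 in SUDHL4, both resistant, and 8.32 and 8.25 in Farage and SUDHL6, with 5.56 or less elsewhere.

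Within the 4 near-identical lines, 132 genes differed by over 2-fold between the pair OCI-Ly4 and OCI-Ly10 and the pair OCI-Ly3 and OCI-Ly18 while differing by less than 2-fold within each pair. Interferon-stimulated genes had 31 of 32 members higher in OCI-Ly4 and OCI-Ly10, with a median difference of 1.03. MX2 differed by 2.41, IFI27 by 2.25 and RSAD2 by 2.08. Cholesterol biosynthesis genes had 0 of 19 members higher there (median -0.83), with HMGCS1 at -1.87, and replication-dependent histones 0 of 24 (median -0.57). SMAD1 was at 6.54 in the first pair and 9.38 in the second. Many lists parted the pairs: among 10000 random lists matched on mean level, 8 of 30 medians lay at percentile 0 or 100. These were interferon, MHC class II, glycolysis and germinal centre genes at 100, and cholesterol, histone, amino acid response and B-cell identity genes at 0, followed by ribosomal protein genes at 0.01. The random lists were drawn gene by gene, so they leave out that genes of a list move together, and the percentiles can overstate the differences. Over the 14 lines the estimated correlation within a list was 0.38 for interferon, 0.59 for cholesterol and 0.52 for histone genes. The comparison of the pairs describes these 4 arrays only, since the pairs were chosen from the data.

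A hypothesis of a shared medium, since OCI-Ly4 and OCI-Ly10 were grown in Iscove's medium, was tested on OCI-Ly1, the 1 line outside the 4 in that medium. Over the 132 genes the correlation of its deviation from the other lines with the difference between the pairs was -0.165, below the median of -0.0747 for the 9 other lines. That met the bound set beforehand against the hypothesis, but a single line excludes nothing, so it stays open.

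A second hypothesis was that OCI-Ly3 holds a small share of activated B-cell-like cells. It arose because OCI-Ly3 exceeded OCI-Ly18 at CD44 (7.11 against 4.82), CCND2 (7.69 against 5.08) and IRF4 (7.36 against 5.72). CD44, CCND2 and IRF4 are also on the marker list tested, so that list was not independent of what prompted the hypothesis. CYB5A differed too (6.70 against 3.83), but it is not on that list, and its median over the 14 lines was 9.08. The median difference of 22 activated B-cell-like markers was 0.03, at percentile 87.6 of 10000 random lists matched on mean level, under the bound of 95 set beforehand. Because 12 of the 22 members were higher and the others lower or equal, this median cannot decide on a small share, which may remain.

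Features 7896697 and 7896715 were at 10.46 or above in all 8 sensitive lines and 5.75 or below in all 6 resistant lines. Both groups occur within the run of 9 arrays and within the run of SUDHL4 and SUDHL6, and the features separated the lines in each. Their identity was not established. Whether they are control features of the array could not be read from the annotation used, and no explanation was tested.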
